A study of Aplysia californica with 8 samples.

How the data were processed

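RNA of cultured Aplysia californica sensory neurons was measured on 4 2-colour oligonucleotide arrays, each carrying cell body RNA in one channel and process RNA in the other. The 8 samples, 4 of cell bodies and 4 of processes, are the channels of these arrays. Per the labels' protocols, dissociated sensory neurons were cultured for 4 days at 8 to 10 neurons per dish, either the cell bodies or the processes were removed from a dish by hand with glass microelectrodes, and what stayed behind was extracted with Trizol. The RNA was amplified in 2 rounds of in vitro transcription and labelled with Alexa Fluor 546 or Alexa Fluor 647, per the labels. All 4 cell body samples carried Alexa Fluor 546 and all 4 process samples Alexa Fluor 647. The series' design text speaks of reciprocal hybridisation, but in the labels of these 8 samples each compartment has 1 dye. Whether arrays with the dyes exchanged were made, and then left out or averaged into these columns, is not given in the sources used here. The values are read as the labels give them, and on that reading a dye effect and a compartment effect cannot be told apart. That text also calls the 4 samples of a compartment biological replicates; whether the cell body and process RNA of 1 array came from the same animals is not stated in the labels.

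The arrays were read with Agilent Feature Extraction, per the submitters' processing notes (version not given in the sources used here). The values the authors deposited are on a log2 scale, one column per channel. The scale was read from the values, which ran from -7.49 to 17.7: as natural or decimal logarithms they would exceed what a scanner records. The background correction, the dye normalisation and the meaning of a blank cell are not given in the sources used here. The deposited log2 columns had medians within 0.18 of one another and were not centred per feature. The medians were 5.34 to 5.41 in the cell body columns and 5.23 to 5.28 in the process columns. How far levels are comparable between the 2 channels is therefore not known. The table has 43693 numbered features (numbers 12 to 45209) and 2698 blank cells, and gives no background flags or saturation flags. Array values have no read depth; the number of arrays limits their precision.

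The files do not pair the feature numbers with probe sequences, accessions or gene names, and none of the 21514 genes of the RefSeq table of assembly AplCal3.0 carries such a number as its identifier (0 matches). The 20 gene lists fixed before the data were examined (ribosomal proteins, cytoskeleton, synaptic proteins, nuclear proteins, markers of muscle, blood cells and glia, and others) therefore had no members that could be matched, and neither they nor sensorin, actin and tubulin are analysed here. Results are given for features. A feature is 1 spot of the array; several features can report on the same transcript, so counts of features are not counts of genes.

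The comparison was process minus cell body with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, Benjamini-Hochberg adjusted p under 0.05), on the deposited log2 values, with the array as a fixed block. The rule set before the data were examined was to use the values as deposited where the column medians lay within 0.25. A feature was tested where at least 2 arrays had both channels, since with 1 array no residual degrees of freedom remain; 385 features were not tested, 117 of them blank in all 4 samples of a compartment and 268 with 1 complete array. The pairing comes from the labels, which put the cell body and process samples of 1 number on 1 array. Over 42201 complete features, the deviations of the paired samples from their compartment means correlated at r = 0.19, 0.03, -0.06 and -0.07 for arrays 1 to 4 (across features, which are not independent replicates), so the deviations themselves showed little pairing. Samples were compared on single values with an exact permutation test over the 8 samples (two-sided, smallest possible p 0.0286) and an exact sign-flip test over the 4 arrays (smallest possible p 0.125). Some thresholds were chosen after the data were seen: a mean log2 signal of 8 or more for bright features and below 5 for dim ones, a level of 10 for strong features, and 8 and 6.5 for features high in one compartment and low in the other.

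The features named follow a rule fixed before the data were examined: with no gene names, the 2 called features with the largest positive and the 2 with the largest negative log2 difference. Data were simulated for the process versus cell body comparison, with 43693 features and the spread of the real ones. The fit called 60% of 100 features changed by 2 on the log2 scale and 72% of 100 changed by 4. None was in the wrong direction, and there were 13 false calls among all others. Without the block it called 72% and 79%, with 15 false calls. The simulated noise was independent between features and samples, with no array effect and no trend along the feature numbers. The gain without the block therefore follows from that setting, and the false calls do not carry over to the real data. Changed features were drawn at random from all features, so the rates do not describe bright features, whose spread is larger.

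Alternatives set in advance were the fit without the block or with the array as a random effect, loess normalisation within arrays (span 0.3) with quantile scaling of the average signal between arrays, centring on the median, quantile normalisation, scaling to the 75th percentile, leaving out the dimmest 25% or 50% of features, a floor at the 10th percentile of all values (3.89), other variance moderation, an adjusted p under 0.01, and leaving out arrays or samples. Where a feature's blank left only 1 channel, loess kept that channel as deposited. Others were added after the data were seen: blanks set to the floor, complete features only, a correction for the trend along the feature numbers, fits on bright features alone, centring on bright features, and other levels for each threshold.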

Results

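The data came from sensory neurons of the sea slug Aplysia californica, a preparation in which the cell body and the outgrown processes of identified neurons can be separated by hand. RNA left in the dish after removal of the processes (cell bodies, n = 4) was compared with RNA left after removal of the cell bodies (processes, n = 4). Each array held one sample of each. The table gave 43693 array features. Blank cells numbered 294, 60, 903 and 407 in cell body samples 1 to 4 and 233, 180, 361 and 260 in process samples 1 to 4. The column medians were 5.38 ± 0.03 (SD, n = 4) in cell bodies and 5.25 ± 0.02 (SD, n = 4) in processes on the log2 scale. P-values measure the spread between these samples and arrays. Per the labels, all process samples carried one dye and all cell body samples the other, so each difference below is read as one between compartments and between dyes at once. The design text, however, speaks of reciprocal hybridisation.

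The design asks which transcripts differ in abundance between the processes and the cell bodies of the same kind of neuron. Among the 6073 bright features, those with a mean log2 signal of 8 or more, 5893 were tested and 743 (12.6%) passed the test. Of these, 492 were higher in processes and 251 higher in cell bodies as deposited. The majority turned to cell bodies (277 against 427) after loess normalisation within arrays and (283 against 580) after quantile normalisation. Loess centres the channel difference at each signal level and quantile normalisation equalises the columns, so both largely remove a common shift by construction. The turn is therefore not a test of the direction. Of the called bright features, 437 were at least 2-fold higher in processes and 207 at least 2-fold higher in cell bodies. The median size of a called difference was 1.75 on the log2 scale, a value that the test itself raises, since with a median standard error of 0.52 over all bright features small differences do not pass. Among bright features as deposited, the excess of calls toward processes was greatest at mean signals of 10 to 12, with 163 features higher in processes and 42 in cell bodies, and of 12 to 14, with 75 and 16. At 8 to 10 the numbers were 217 and 171, and at 14 or more 37 and 22. The split by level was not examined under loess or quantile normalisation.

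Calls were made with limma at an adjusted p under 0.05 over all features tested. The count of bright calls rested on the number of arrays: it was 212, 398, 397 and 279 without array 1, 2, 3 and 4. Without array 1 the share of bright calls higher in processes fell from 66.2% to 39.6%, while it was 66.8%, 69.0% and 63.4% without array 2, 3 and 4. The count was 1340 in the fit without the array block and 234 when bright features were fitted alone.

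Over all features, 13221 of 43308 tested (30.5%) passed, 7300 higher in processes and 5921 higher in cell bodies, and 3276 of them differed at least 2-fold, 957 toward processes and 2319 toward cell bodies. Most of these calls lay among dim features. Features with a mean log2 signal below 5 gave 6707 calls, 50.7% of all, of which 7.77% reached 2-fold; the median size of a called difference there was 0.37, and the median standard error of a dim feature 0.06. Below a mean of 4, 65.4% of the features tested were called, against 13.8% at 8 to 10 and 7.96% at 14 or more. Dim values repeated closely between the cell body samples, with a median SD of 0.03 for features below 5 and 0.69 for bright ones, and in processes of 0.11 and 0.74. In all, 23098 features had an SD under 0.05 over the cell body samples and 5130 over the process samples. Of the 2319 features at least 2-fold higher in cell bodies, 579 had a process mean under the 10th percentile of all values (3.89), while 8 of the 957 toward processes had a cell body mean under it. The total fell to 5242, 6910, 6577 and 4250 calls without array 1, 2, 3 and 4, of which 1639, 2442, 2150 and 1802 were at least 2-fold, and to 3172 when the dimmer 50% of features were left out. The share of all calls that were higher in processes was 55.2% as deposited, 47.9% after loess, 75.5% after median centring, 70.5% after quantile normalisation and 84.8% after scaling to the 75th percentile.

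**Figure D1:**
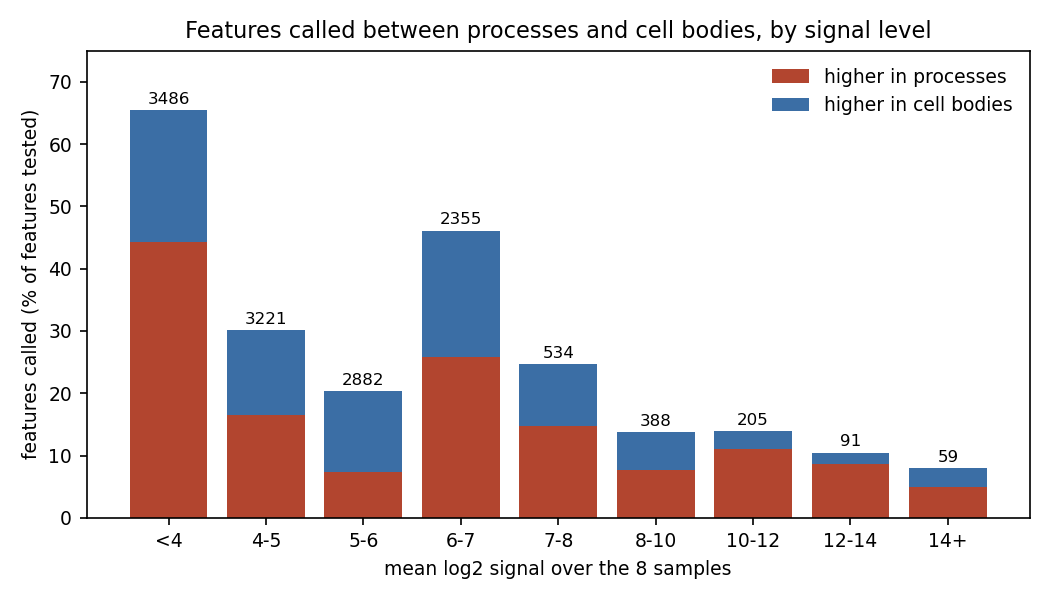
Features called between processes and cell bodies as a percentage of the features tested, by the mean log2 signal over the 8 samples; red is higher in processes, blue higher in cell bodies, and the number of calls stands above each bar. The called share is 65.4% below a mean of 4 and 7.96% at 14 or more, and among bright features red exceeds blue as deposited. That split turns under loess and quantile normalisation, which take off much of a common shift by construction.

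The differences of dim features followed the feature number, which Agilent software assigns in order over the array. In 20 consecutive blocks of features with a mean below 5, the median log2 difference ran from -0.23 to 0.31, a span of 0.54, while 1000 shuffles of the feature order gave spans of up to 0.10. The 6 outer blocks lay between -0.23 and -0.13 and the 9 middle blocks between 0.18 and 0.31. Each array's block medians followed their mean over arrays with r of at least 0.98. Bright features gave block medians from 0.37 to 0.65, a span of 0.29, inside what shuffling gave (median 0.31, highest 0.61). With each array's trend along the feature numbers taken off, 9056 features were called, 7801 of them also called before; 4378 were dim, of which 3281 were also called before, and 565 bright.

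**Figure D2:**
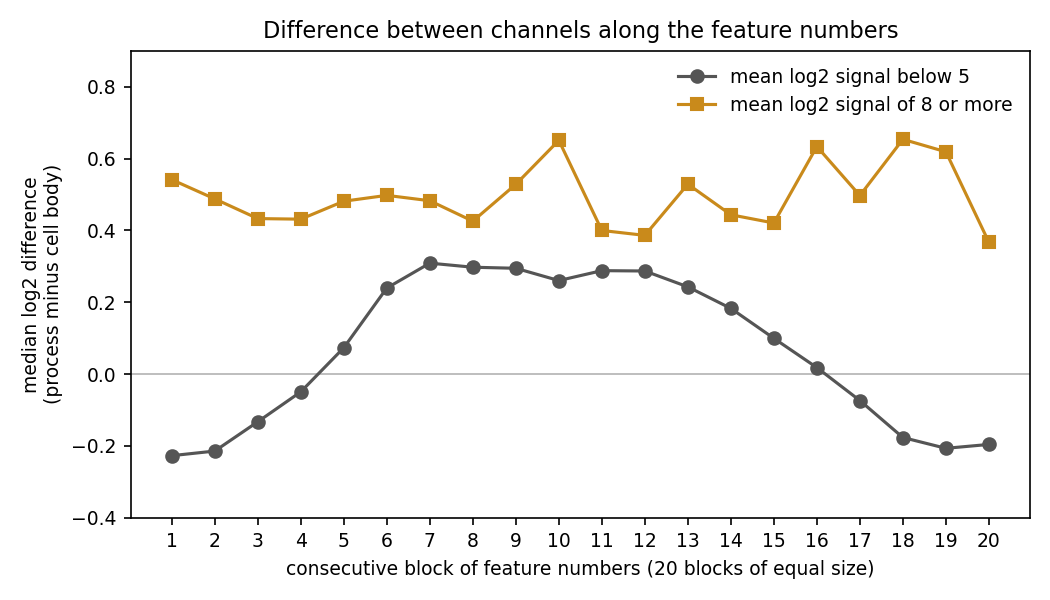
Median log2 difference, process minus cell body, in 20 consecutive blocks of feature numbers, for features with a mean log2 signal below 5 (grey) and of 8 or more (orange). Dim features run from -0.23 to 0.31 along the array, and bright features stay between 0.37 and 0.65 with no such course.

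Process samples held more strong features. Features with a log2 signal of 10 or more numbered 3697.5 ± 96.9 (SD, n = 4) in processes and 2859.8 ± 147 (SD, n = 4) in cell bodies, a difference of 838 (exact permutation test, two-sided, p = 0.0286, the smallest 4 against 4 samples can give; adjusted p = 0.05 over 7 such measures). It was 487 after loess within arrays (exact permutation p = 0.0286). A blank cell counted as below the level. In the cell body columns 942 blank cells faced a process value in the top 10% of its column. In the process columns 25 blank cells faced such a cell body value. How much of the difference in strong features came from blank cells was not examined. Quantile normalisation largely removes such a difference by construction, so it was not counted there. As deposited, the difference was positive on all 4 arrays, for which the exact sign-flip test gave p = 0.125, its smallest value. At a level of 12, 1948 ± 139 (SD, n = 4) features in processes stood against 1438 ± 150 (SD, n = 4) in cell bodies, with the same p-values. At a level of 8 the counts were 6299.5 ± 143 and 6110.5 ± 94.6 (SD, n = 4 each; exact permutation p = 0.114), a difference within the spread between samples. The 90th percentile of the log2 signal was 9.42 ± 0.05 in processes and 8.90 ± 0.02 in cell bodies (SD, n = 4 each; exact permutation p = 0.0286), while the column median differed the other way, by -0.13 (exact permutation p = 0.0286). The contrast depends on the part of the distribution that is compared. Bright features had a median log2 difference of 0.44, 0.18, 0.53 and 0.52 on arrays 1 to 4, a mean of 0.42 ± 0.17 (SD, n = 4 arrays; exact sign-flip p = 0.125), which was 0.01 after loess and -0.19 after quantile normalisation. Both methods take off much of such a shift by construction, so neither value tests its direction. The 100 strongest features took 17.6% ± 3.84 of the linear signal in processes and 21.2% ± 2.50 in cell bodies (SD, n = 4 each; exact permutation p = 0.2), which did not exceed the spread between samples.

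**Figure D3:**
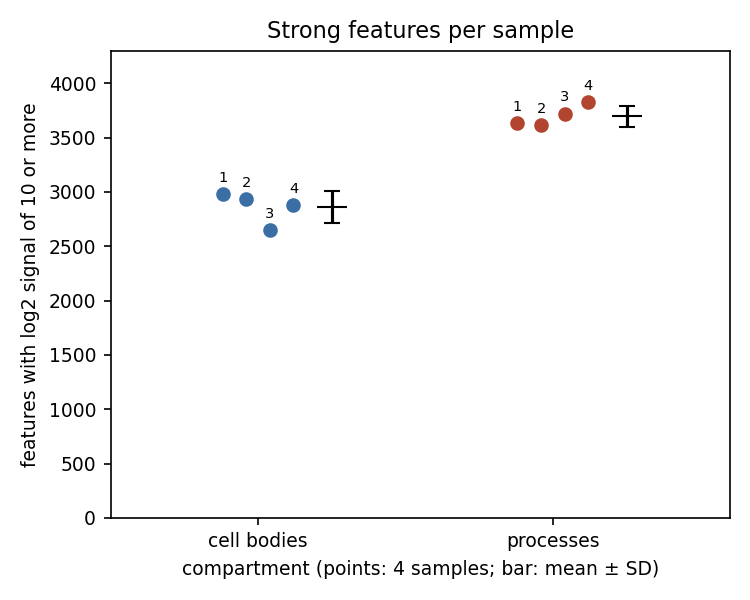
Number of features with a log2 signal of 10 or more in each of the 8 samples, numbered by array, with the mean and SD of each compartment beside the points. The 4 process samples lie between 3613 and 3824 and the 4 cell body samples between 2649 and 2981.

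Most features strongly detected in all samples of one compartment were so in the other, but few of the 100 strongest were shared. Of the 4865 features at 8 or more in all 4 process samples, 3407 (70.0%) were at 8 or more in all 4 cell body samples too, which was 81.3% of the 4191 features at that level in all cell body samples; independent lists would share 467. Features at 8 or more in every sample of one compartment and below 6.5 in every sample of the other numbered 20 for cell bodies and 0 for processes. Without array 1, 2, 3 and 4 in turn they numbered 43, 54, 28 and 44 for cell bodies and 4, 4, 6 and 6 for processes. When blank cells were counted as low, they numbered 22 for cell bodies and 103 for processes, so over all 4 arrays every process feature of this kind had a blank cell body value. Without array 1, 2, 3 and 4 in turn the process count with blanks as low was 116, 280, 103 and 112, and the cell body count 49, 61, 30 and 51. The excess of processes depended on the levels: at 7 or more against below 6, with blanks as low, 162 features stood for processes and 206 for cell bodies. Of the 100 features with the highest mean, the compartments shared 6, against 0.23 expected of independent lists. Of the top 500 they shared 329 (65.8%, against 5.72 expected), and of the top 1000, 813 (81.3%, against 22.9 expected). Both channels read the same probes, so their lists could not be independent. Overlaps above those of independent lists, here and at the level of 8, therefore do not test sharing of transcripts. Of the top 100 in processes, 13 were called, and of the top 500, 37, so most of these strong features did not pass the test. Of the top 1000 in processes, 94 were called, 80 of them higher in processes and 14 higher in cell bodies. The lists were chosen by process level, so their direction is not independent of that choice. Overlap between samples of one compartment was not examined, so the 6 shared of the top 100 have no baseline for the spread between samples.

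Over all features, samples of a compartment resembled one another more than samples of different compartments. Pearson's r between samples was 0.92 to 0.96 within cell bodies, 0.92 to 0.96 within processes and 0.82 to 0.91 between compartments on different arrays. Among bright features the ranges were 0.83 to 0.92, 0.80 to 0.91 and 0.64 to 0.84, and the 2 channels of 1 array correlated at 0.61 to 0.83. These ranges overlap: some pairs from different compartments correlated more closely than some pairs within one. These correlations are across features, which are not independent replicates.

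The largest differences among the calls belonged to features whose weaker channel was blank or near the bottom of the scale, so their folds depend on how low values are treated. Feature 39441 had a log2 signal of 12.2 ± 0.93 (SD, n = 4) in processes and 2.88 ± 0.35 (SD, n = 2, 2 blank) in cell bodies, a difference of 8.61 ± 0.07 (SE, 2 complete arrays; limma adjusted p = 0.0049). Feature 531 had 12.2 ± 0.92 (SD, n = 4) and 3.54 ± 0.84 (SD, n = 2, 2 blank), a difference of 8.04 ± 0.27 (SE; limma adjusted p = 0.013). Process samples 1 to 4 read 11.7, 12.2, 13.4 and 11.3 for feature 39441 and 11.8, 12.3, 13.5 and 11.4 for feature 531. Whether these 2 features report on the same transcript was not tested. In the other direction, feature 30956 had 6.79 ± 1.04 (SD, n = 4) in cell bodies and -0.62 ± 0.27 (SD, n = 2, 2 blank) in processes, a difference of -8.29 ± 0.34 (SE; limma adjusted p = 0.015), and feature 28399 had 5.31 ± 0.70 and -1.70 ± 1.24 (SD, n = 4 each), a difference of -7.01 ± 0.84 (SE; limma adjusted p = 0.012). With blanks and low values set to the 10th percentile, the log2 differences were 8.26 and 8.29 for the features higher in processes. This takes the 2 blank cell body values of each as low signal, which is not known, so these sizes are in part set by the fill. For the features higher in cell bodies the differences were -2.89 and -1.42, and feature 28399 no longer passed (limma adjusted p = 0.0504). That feature also missed the threshold without array 3 (limma adjusted p = 0.052) and without array 4 (limma adjusted p = 0.060), with differences of -7.04 and -7.15. Features 39441, 531 and 30956 had 2 complete arrays each, so leaving out an array could not challenge them in this way.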

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

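Calls were made under every setting run, but their number and their split between the compartments moved. Results on bright features, strong features, features high in one compartment only and position were defined after the data were seen, as were all settings on bright features, blanks and position. The 13221 calls became 5115 and 3172 without the dimmest 25% and 50% of features and 3909 at an adjusted p under 0.01; they stayed within 1.5 times under the other settings fixed in advance that kept all samples, including 17398 with no replicate block and 18574 with a random replicate block, for the array pairs. Centring on bright features gave 29639 calls, since a common shift moves dim features past their small standard errors. Calls higher in processes (7300) became 12353 after median centring, 11378 after quantile normalisation, 16491 after scaling to the 75th percentile, 2379 and 1407 without the dimmest 25% and 50%, 4450 with a floor, 4761 with blanks at the floor too, 2185 at 0.01, and 946 and 1409 when samples were centred on bright features or arrays shifted by their bright median difference. Calls higher in cell bodies (5921) became 2963 after scaling to the 75th percentile, 2736 and 1765 without the dimmest 25% and 50%, 1724 at 0.01, 3564 with the position trend taken off, and 28693 and 17913 under the bright centring and shift. The 3276 calls of at least 2-fold became 1942 without the dimmest 50%, 2041 without moderation, 1259 at 0.01, and 8395 and 5396 under the bright centring and shift. The 743 bright calls became 1340 with no replicate block and 1493 with a random one, 1197 after scaling to the 75th percentile, 469 and 438 without the dimmest 25% and 50%, 248 without moderation, 69 at 0.01, 234 when fitted alone, 1277 and 355 with bright set at 7 and 10, and 1566 and 1144 under the bright centring and shift. The median difference of bright features (0.42) was 0.010 after loess, 0.68 after scaling to the 75th percentile and, reversed, -0.19 after quantile normalisation. Loess and quantile normalisation take off much of such a shift by construction. Counting blanks as low, features high in processes only (103) were 36 and 162, and those high in cell bodies only (22) were 0 and 206, at levels of 9 and 6 and of 7 and 6. Apart from fewer samples, fewer features and the common shift, the cause of these changes was not tested.

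Leaving out arrays, or single samples in the fit with no replicate block, gave 4250 to 18178 calls, 2164 to 10286 higher in processes, 2086 to 7892 higher in cell bodies, 1639 to 4341 of at least 2-fold and 212 to 1389 bright calls. It gave median differences of bright features of 0.38 to 0.50, and 103 to 280 features high in processes only against 30 to 61 in cell bodies only. The difference in strong features was 759 to 900.3 with 3 arrays, where the exact test cannot go below p = 0.1, and 487 to 1133 under loess, median centring and scaling to the 75th percentile. Quantile normalisation largely removes it by construction. The share of the strongest 100 features stayed lower in processes, by -2.06 to -4.90 percentage points with 1 array left out. The 4 named features kept their direction under every setting that tested them. Feature 28399 missed the threshold with a floor (-1.42) and without array 3 or 4, and features 531 and 30956 missed it without moderation. Features 39441, 531 and 30956 had 2 complete arrays each. Leaving out an array therefore either left them untested or returned the same difference, so among the named features it could challenge only feature 28399. The set tests on gene lists were not run, because no feature could be matched to a gene.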

Other observations

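Features without a value in one compartment stand outside the tests above. In all, 44 features were blank in all 4 cell body samples, with process means of 7.39 to 14.4 (median 9.51), and 73 were blank in all 4 process samples, with cell body means of 3.70 to 8.52 (median 7.03). Features also resembled one another: of 2835 complete features with a mean of 10 or more, 1698 (59.9%) had another such feature within 0.25 on the log2 scale in all 8 samples, against 206 (7.27%) after the profiles were shuffled among features. Of the 31 sets of 4 values examined for a sample far from the others, 0 held one.

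The tests of blank cells below, of one aberrant array, and of a shift of each array by its bright median difference were chosen after their results or related values were seen; the other tests were chosen once the table had been examined, but before the value each one measures was seen.

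Calls among dim features were numerous and small. A dye curve that depends on level is argued against as the whole cause, since 6309 of such calls were made after loess, against 6707 before. Position on the slide accounts for a part: block medians along the feature numbers spanned 0.54 on the log2 scale in the same course on every array. Whether it is the whole stays open: with that trend taken off, 3281 of the 6707 dim calls (48.9%) remained, slightly under the bound set before that run, but 1097 others were newly called, and the total of 4378 was above that bound. A dye or background difference per feature that repeats on all arrays may account for others; it and a true compartment difference cannot be told apart, because per the labels 0 of the 4 arrays had the dyes exchanged.

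The higher median signal of bright features in processes was seen on each array, with median differences of 0.44, 0.18, 0.53 and 0.52, so it did not rest on one of them. The mean median difference was at least 0.38 without any one array. With every array positive that mean could not turn negative, so leaving arrays out was no further test of an aberrant array. Which compartment led the bright calls was less firm. With no change of scaling, 66.8%, 69.0% and 63.4% were higher in processes without array 2, 3 and 4, but 39.6% without array 1. The share was also 42.4% after each array was shifted by its bright median difference and, outside the range set before that run, 30.1% after each sample was centred on its bright features, but such centring largely sets the split by construction, so a normalisation anchored on dim features is neither excluded nor borne out. A dye response or amplification that differs between the channels at high signal, and a real difference in RNA composition, also stay open, because per the labels 0 of the 4 arrays had the dyes exchanged.

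Blank cells fell on other kinds of features in the 2 compartments. In cell body columns, dim signal is argued against for a large part. Of the 1488 blank cells with a value in another cell body sample, 54.9% averaged 7 or more there. Saturation is argued against too, since 6.79% of all blank cells in these columns had a value or mean of 14 or more (3.68% to 8.18% without any one array). The blank share there was 196 times higher where the process value was in the top 10% of its column than below its median (5.42% against 0.03%), which a correction that takes off a part of the other channel may produce. Its size is loose, as the lower share rests on 24 blank cells and the ratio was 141 to 410 without any one array. In process columns that ratio was 1.02, and 0.27 without array 3, which held 20 of the 25 blank cells with a partner in the top 10%, but 85.7% of blank cells had a cell body value between the median and the top 10%, where the blank share was 1.28% against 0.14% below the median, so whether such a correction acted there stays open. Of the 742 process blank cells with a value in another process sample, 9.30% averaged 7 or more there, as dim signal would give; for the other 292 this could not be tested. Features high in processes and blank in cell bodies are therefore weak evidence of absence from cell bodies.

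Chance assignment of samples was tested by regrouping. In the fit without the array block, 1 of the 35 splits of the 8 samples into 4 and 4, the real one, gave as many calls (17398), as many higher in processes (9806) or in cell bodies (7592), as many of at least 2-fold (4296) and as many bright calls (1340). The highest of the other splits gave 3 in each case. A share of 1 in 35 is the smallest these splits can give, they leave out the array pairing, and the counts overlap. Chance is argued against for these counts, but not excluded. With the block, the 8 splits that part the channels of every array are too few for a share under 0.05. There the real split gave 13221, 7300, 5921, 3276 and 743, and the highest of the others 0. None of this separates compartment from dye, which follow the same split in the labels.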
